A study of Mus musculus with 4 samples.

How the data were processed

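Gene expression was measured in 4 samples of cultured mouse cells on single-colour arrays with biotin-labelled RNA. The titles put 2 samples in the group Hemangioblast and 2 in the group hCD4, and each title carries a replicate number. Per the labels, total RNA was extracted with TRIzol without amplification, and 20 ug was reverse transcribed and labelled. The authors deposited 1 linear intensity per probe set and array. The software, background correction and scaling behind these intensities are not given in the sources used here. On each array 1.16 to 1.27% of the values were exactly 1, and the trimmed mean intensity ran from 334 to 389, so the arrays had not been brought to one trimmed mean. All 4 value columns were used and 0 were left out.

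Of 12488 probe sets, the 66 controls of the array maker were left out, and 12422 were tested. Each array was scaled to the average of the arrays' trimmed means, with 2% of the values trimmed at each end, and the scale factors were 0.938 and 1.05 for the Hemangioblast arrays and 0.936 and 1.09 for the hCD4 arrays. Log2 of the scaled intensity plus 16 was taken. Scaled intensities are given as mean ± SD of 2 arrays, while changes, their standard errors (SE) and folds are those of the log2 values with the added 16, so they are smaller than the ratio of the means where a gene is dim. No filter on dim probe sets was used in the reported fit.

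Genes were named from the array platform's annotation. Of the tested probe sets, 10833 have 1 gene symbol, 396 have several and 1193 have none there. The symbols were checked through gene identifiers against a reference table, which held 10817 of those with 1 symbol and changed 0 symbols. No gene is named from a probe set with several symbols. A gene with more than 1 probe set (2073 of 8251 genes) is represented by the probe set with the highest mean over the 4 arrays. Apart from that choice, levels of different probe sets are not compared with each other, and no genome coordinates are given.

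The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), as Hemangioblast minus hCD4, with 2 arrays in each group and no block. The fit had 2 residual and 6.18 prior degrees of freedom. The test is two-sided, p-values were adjusted by Benjamini-Hochberg over the 12422 probe sets, and the threshold was an adjusted p of 0.05. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so none was used. A second count took the probe sets that differed at least 2-fold in the same direction in all 4 comparisons of a Hemangioblast array with an hCD4 array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

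Before the data were examined, 21 gene lists were written from general knowledge of pluripotent, mesodermal, blood, endothelial and other lineages and of signalling, growth and stress. Together they hold 529 distinct genes, of which 442 were measured. A list's shift against all other genes was tested with limma's camera on 1 probe set per gene, two-sided, with a preset correlation of 0.01, and adjusted over the 21 lists. It was tested again with a correlation estimated from each list. Camera then takes its p-value on the 2 residual degrees of freedom of the fit, while with the preset correlation these follow the number of genes. Members past the threshold were counted over all probe sets and again adjusted over the list alone. A list needed at least 5 measured members.

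The named genes were also chosen by a rule fixed before the data were examined. They are the 10 genes with the largest change in each direction among those past the threshold whose groups do not overlap, the genes Kdr, Tal1, Gata2, Lmo2, Runx1, T, Pou5f1 and Nanog whatever their values, and in each list up to 4 members with the smallest adjusted p. Genes named outside this rule are marked as chosen after their values were seen. For 98 named genes a value was found, and 69 of these passed the threshold.

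The fit was tested on 20 sets of simulated arrays with 200 changed probe sets each, drawn from those brighter than the median, with noise modelled on the arrays of a group. It recovered 0.499% of changes of 1.5-fold, 10.9% of 2-fold and 84.2% of 4-fold, and 5.34% of its calls were false. The real comparison called 556 probe sets, more than the 200 changed here, and the adjustment is less strict where more are called. The recovered shares therefore need not hold for the real comparison. With no simulated change it called 0 probe sets on average. Lists of 25 probe sets with a log2 shift of 0.5 had an unadjusted camera p under 0.05 in 20 of 20 simulations, and lists with no shift in 0. The simulated noise was independent between probe sets, while estimated correlations of the real lists reached 0.399 (heme synthesis and iron uptake). The simulation therefore does not test the list calls where members are correlated. The alternatives tried were an added constant of 1 or 64, median scaling, no scaling, quantile normalization, leaving out dim probe sets, eBayes without the trend, limma's treat with a minimum fold of 1.5, pairwise folds of 1.5 and 4, the mean of a gene's probe sets, an estimated correlation, the replicate number as a block, and leaving out each array in turn.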

Results

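RNA from 2 mouse cell populations was measured on single-colour oligonucleotide arrays of 12488 probe sets, with 2 arrays per population. The cells came from an embryonic stem (ES) cell line in which human CD4 reports the expression of Scl, the transcription factor encoded by Tal1. Per the labels, these ES cells were differentiated for 2.75 days into embryoid bodies, from which cells positive for Flk-1 (the VEGF receptor encoded by Kdr) and for Scl were sorted as hemangioblasts, the common precursors of blood and endothelium. Embryoid body cells were also replated, and the blast colonies that grew were picked and pooled. The array titles name the populations Hemangioblast and hCD4, the sample sources call them differentiated hemangioblasts and cultured hCD4 ES cells, and the study text calls the same 2 populations hCD4 and Blast. The name hCD4 stands in both the titles and the study text, which leaves Blast for the arrays titled Hemangioblast. The sources name ES cells and hemangioblasts instead, so the labels differ on which arrays hold sorted cells, colonies or ES cells. The groups are therefore called here by their array titles alone. If the Hemangioblast arrays held the blast colonies and the hCD4 arrays the sorted cells, which the names allow, each log2 change below would be colonies minus sorted cells. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

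The median intensity per array was 193 and 197 for the Hemangioblast arrays and 197 and 165 for the hCD4 arrays, before scaling. Log2 intensities of the 2 Hemangioblast arrays correlated across probe sets with Pearson's r of 0.961, those of the 2 hCD4 arrays with 0.963, and arrays of different groups with 0.921 to 0.940. These correlations run across probe sets, which are not independent replicates. The 3' to 5' signal ratio of the Gapdh control, a measure of RNA integrity, was 1.33 and 1.03 on the Hemangioblast arrays and 1.13 and 1.03 on the hCD4 arrays. For the actin control the ratio was 1.63 and 1.16 against 1.36 and 1.12. The number of arrays limits the precision of every value, and the median standard error of a log2 change was 0.27.

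The comparison of the 2 populations asks which genes distinguish them along the path from ES cells through hemangioblasts to blood. Genes of blood cells were higher on the Hemangioblast arrays, with 17 of 30 measured myeloid genes and 10 of 19 erythroid genes past the threshold and 0 lower. The shifts of both lists passed (camera adjusted p = 2.91e-18 and 5.54e-11, and adjusted p = 0.289 for each with an estimated correlation). Ccl9, a chemokine of myeloid cells, had a scaled intensity of 2362 ± 249 (SD, n = 2) on the Hemangioblast arrays and 38.6 ± 0.867 on the hCD4 arrays, a log2 change of 5.44 (SE 0.196, adjusted p = 2.69e-05). The embryonic beta-like globin Hbb-bh1 was at 7637 ± 496 against 1322 ± 1.28, a log2 change of 2.51 (SE 0.137, adjusted p = 9.5e-05). Of 22 measured regulators of the hemangioblast stage, 4 were lower on the same arrays and 0 higher (camera adjusted p = 0.000241, and adjusted p = 0.309 with an estimated correlation). Kdr, the Flk-1 gene of the sort, was at 609 ± 55.0 against 1814 ± 267, a log2 change of -1.54 (SE 0.168, adjusted p = 0.00158). Etv2, a transcription factor that starts the blood and endothelial program in mesoderm, was at 27.7 ± 12.3 against 433 ± 14.9, a log2 change of -3.39 (SE 0.309, adjusted p = 0.000703). Changes are Hemangioblast minus hCD4 throughout.

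In all, 442 of 8251 genes passed an adjusted p of 0.05, of which 280 were higher and 162 lower on the Hemangioblast arrays. At least 4-fold changes were found for 91 of the higher and 13 of the lower genes. Counted as probe sets, 556 of 12422 passed (362 higher, 194 lower), and 2029 had an unadjusted p under 0.05. The study text says that pairwise comparisons were made, and the rule of size used here was set for this report. By this rule, 359 probe sets differed at least 2-fold in the same direction in all 4 pairs of arrays (284 higher, 75 lower). Of these, 324 were also among the 556. For 5521 probe sets (44.4%) the arrays of the groups did not overlap, where chance gives 33.3%. Without Hemangioblast replicate 2, hCD4 replicate 1 or hCD4 replicate 2 the count of 556 probe sets was 369, 268 and 219, without an intensity trend in the variance model it was 220, and without scaling between arrays it was 272 (222 higher, 50 lower). Of 69 named genes past the threshold, 36 stayed past it under every setting that uses all 4 arrays and tested them. Fewer did so when each array was also left out in turn. Genes on dim probe sets were not tested where dim probe sets were left out.

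**Figure D1:**
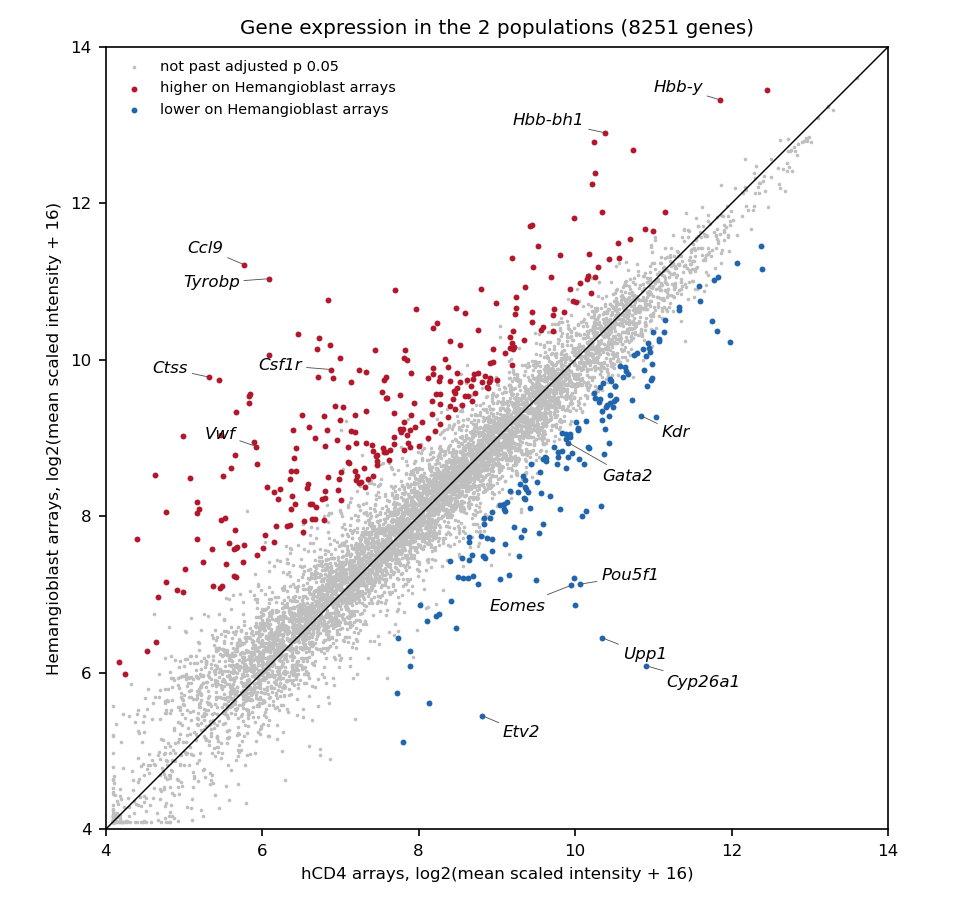
Mean scaled intensity of 8251 genes on the 2 hCD4 arrays (horizontal) and the 2 Hemangioblast arrays (vertical), each as log2 of the mean plus 16. Each point is 1 gene, the line marks equal values, and the coloured points are the 280 genes higher and 162 genes lower on the Hemangioblast arrays at an adjusted p under 0.05, with Ccl9 and Tyrobp farthest above the line and Cyp26a1 and Etv2 among the farthest below it.

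Genes of macrophages and other myeloid cells were among the 10 that rose the most. After Ccl9 came Tyrobp, a signalling adaptor of myeloid and natural killer cells (log2 change 4.95, SE 0.202), Ctss, a lysosomal protease of antigen-presenting cells (4.46, SE 0.260), the myeloid receptor gene Lilr4b (4.33, SE 0.289), the pan-leukocyte gene Ptprc, which encodes CD45 (4.17, SE 0.424), and the lectin gene Lgals3 (4.07, SE 0.352). They were followed by the chemokine gene Ccl6 (3.93, SE 0.205), Lpl, which encodes lipoprotein lipase (3.90, SE 0.246), Adgre1, which encodes the macrophage antigen F4/80 (3.90, SE 0.362), and the annexin gene Anxa1 (3.75, SE 0.302). Their adjusted p-values lay between 2.69e-05 for Ccl9 and 0.0011 for Ptprc. Mean scaled intensity on the hCD4 arrays was 8.64 for Adgre1 and 15.6 for Ptprc, near or below the constant of 16 added before the log, which therefore sets part of their change. Another probe set of Adgre1 (log2 change 0.15, adjusted p = 0.947) and further ones of Ptprc (adjusted p of 0.0766 and 0.644) did not pass.

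In the myeloid and macrophage list, 17 of 30 measured genes rose and 0 fell over all probe sets, and 18 rose and 0 fell when adjusted over the list alone. The median log2 change of the list was 1.67 (camera adjusted p = 2.91e-18, and adjusted p = 0.289 with an estimated correlation). Csf1r, the receptor for the macrophage growth factor CSF1, was at 923 ± 167 against 102 ± 16.1 (log2 change 2.99, SE 0.225, adjusted p = 0.000333). The leukocyte tetraspanin gene Cd53 was at 631 ± 129 against 34.8 ± 3.99 (3.66, SE 0.270, adjusted p = 0.000317). Another probe set of Csf1r had a log2 change of 0.26 (adjusted p = 0.865).

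Erythroid genes formed the other large rise. Of 19 measured members of the erythroid list, 10 rose and 0 fell, and 12 rose and 0 fell when adjusted over the list alone. The median log2 change was 0.99 (camera adjusted p = 5.54e-11, and adjusted p = 0.289 with an estimated correlation). The adult alpha-globin gene Hba-a1 was at 7029 ± 650 against 1193 ± 16.1 (log2 change 2.54, SE 0.141, adjusted p = 1e-04). The embryonic globin gene Hbb-y was at 10250 ± 1210 against 3671 ± 220 (1.47, SE 0.149, adjusted p = 0.00108). By another probe set the log2 change of Hbb-y was 2.05 (adjusted p = 0.000414). The probe set annotated to the adult beta-globin gene Hbb-b2, whose paralogs have closely similar sequence, was at 1231 ± 170 against 89.4 ± 46.1 (3.63, SE 0.304, adjusted p = 0.000532). In the heme synthesis and iron uptake list, 3 of 13 measured genes rose and 0 fell, with 8 and 0 when adjusted over the list alone (median log2 change 0.51, camera adjusted p = 0.000479, and adjusted p = 0.309 with an estimated correlation). Alas2, the enzyme of the rate-limiting step of heme synthesis in red cells, rose by 1.95 on the log2 scale (SE 0.231, adjusted p = 0.00243). Fech, which inserts iron into the porphyrin ring, rose by 1.25 (SE 0.217, adjusted p = 0.0167) and Alad by 0.81 (SE 0.147, adjusted p = 0.0197). Cpox was at 1703 ± 280 against 1040 ± 47.4, with an adjusted p of 0.0559. With 1 array left out, the adjusted p of Fech was 0.0506 to 0.102 whichever array was missing, and that of Alad reached 0.16 and was above 0.05 without either hCD4 array.

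Some genes of platelets and blood progenitors rose. In the megakaryocyte and mast cell list, 4 of 16 measured genes rose and 1 fell, with 5 and 1 when adjusted over the list alone (median log2 change 0.45, camera adjusted p = 0.00575, and adjusted p = 0.289 with an estimated correlation). Gp1bb, Gp5 and Gp9, components of the platelet receptor for von Willebrand factor, rose by 3.44 (SE 0.315), 2.13 (SE 0.304) and 1.78 (SE 0.278), and the granule proteoglycan gene Srgn by 2.61 (SE 0.396). Their adjusted p-values were 0.000703, 0.00665, 0.0105 and 0.00919. The member that fell, named after its values were seen, was F2r, which encodes a thrombin receptor (-0.85, SE 0.175, adjusted p = 0.0342). Members that did not pass over all probe sets, also named after their values were seen, include the mast cell genes Cma1 (adjusted p = 0.0857), Hdc (0.677) and Cpa3 (0.977) and the platelet gene Pf4 (0.662). Without Hemangioblast replicate 2 the adjusted p of Gp5 was 0.0599, and its other probe set had an adjusted p of 0.512. In the blood progenitor list, 3 of 20 measured genes rose and 0 fell, with 5 and 0 when adjusted over the list alone (median log2 change 0.48, camera adjusted p = 0.000411, and adjusted p = 0.289 with an estimated correlation). Besides Ptprc these were Cd34, a surface marker of blood progenitors and endothelium, at 634 ± 0.276 against 144 ± 7.72 (2.02, SE 0.197, adjusted p = 0.000896), and the homeobox gene Meis1 at 110 ± 2.13 against 9.46 ± 0.865 (2.30, SE 0.331, adjusted p = 0.00686). Mllt3 had a log2 change of 0.87 (SE 0.213, adjusted p = 0.0631). Mean scaled intensity on the hCD4 arrays was 17.6 for Gp1bb, 19.9 for Srgn and 9.46 for Meis1, near or below the added constant of 16, which sets part of their change. With an added constant of 1 the log2 change of Meis1 was 3.40, and with 64 it was 1.24.

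Genes of the early embryo were among the 10 that fell the most. Cyp26a1, which degrades retinoic acid, had the largest fall, from 1898 ± 287 on the hCD4 arrays to 52.1 ± 7.98 on the Hemangioblast arrays (log2 change -4.81, SE 0.211, adjusted p = 4.12e-05). The uridine phosphorylase gene Upp1 changed by -3.87 (SE 0.297), the growth factor gene Fgf3 by -3.08 (SE 0.287) and Eomes, a T-box factor of the primitive streak, by -2.86 (SE 0.264). Pou5f1, which encodes the pluripotency factor Oct4, changed by -2.79 (SE 0.398, adjusted p = 0.00663), from 1056 ± 665 to 124 ± 28.0, and its 2 hCD4 arrays lay far apart at 1526 and 585. The glycine decarboxylase gene Gldc (-2.78, SE 0.191), the Wnt-linked receptor gene Lgr5 (-2.65, SE 0.351), Ablim1 (-2.52, SE 0.304) and the vesicular GABA transporter gene Slc32a1 (-2.34, SE 0.415, adjusted p = 0.0179) completed the 10 largest falls together with Etv2. Mean scaled intensity of Lgr5 on the Hemangioblast arrays was 18.5, near the added constant of 16. Without hCD4 replicate 2 the adjusted p of Slc32a1 was 0.141. Other probe sets of Upp1 (log2 change 0.14, adjusted p = 0.892) and Pou5f1 (0.94, adjusted p = 0.293) did not pass.

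Regulators of the hemangioblast stage fell as a list. The 2 hCD4 arrays also differed from each other in this list (median log2 difference -0.27, replicate 1 minus replicate 2). Of 22 measured members, 4 fell and 0 rose, and 8 fell and 1 rose when adjusted over the list alone (median log2 change -0.44, camera adjusted p = 0.000241, and adjusted p = 0.309 with an estimated correlation). Besides Etv2 and Kdr these were Smad1, a transducer of BMP signals (-1.51, SE 0.185, adjusted p = 0.00296), and Gata2, a transcription factor of blood progenitors, at 475 ± 19.8 against 950 ± 4.14 (-0.98, SE 0.157, adjusted p = 0.0124). Tal1, the Scl gene of the sort, was at 362 ± 41.2 against 646 ± 70.0 and missed the threshold (-0.81, SE 0.186, adjusted p = 0.0513). Lmo2, a partner of Scl, was at 1473 ± 204 against 2191 ± 485 (-0.56, SE 0.189, adjusted p = 0.172), and Runx1, which is needed for definitive blood, was at 192 ± 68.3 against 226 ± 59.0 (-0.24, SE 0.310, adjusted p = 0.810). The adjusted p of Gata2 reached 0.11 with 1 array left out and was above 0.05 without either hCD4 array. Other probe sets of Gata2 (log2 change 0.74, adjusted p = 0.550) and Smad1 (-1.26, adjusted p = 0.061) did not pass.

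**Figure D2:**
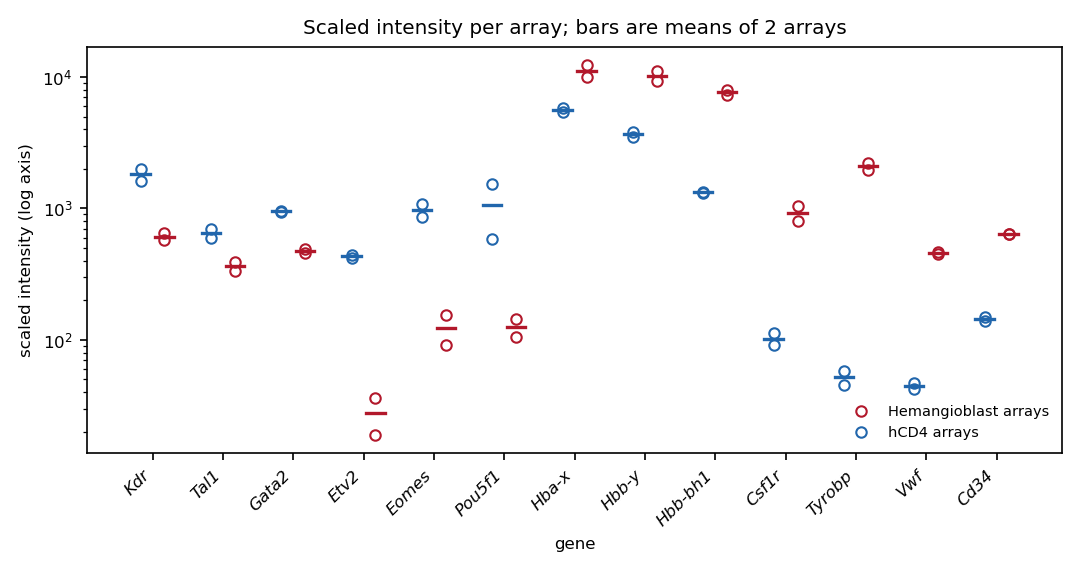
Scaled intensity on a log axis of 13 genes on each of the 4 arrays, with Hemangioblast arrays in red, hCD4 arrays in blue and bars at the mean of the 2 arrays of a group. Kdr, Etv2, Eomes and Pou5f1 lie lower on both Hemangioblast arrays, Hbb-bh1, Csf1r, Tyrobp, Vwf and Cd34 lie higher, and the hCD4 arrays differ most from each other for Pou5f1 (1526 and 585).

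In the pluripotency list, 4 of 27 measured genes fell and 0 rose, with 8 lower and 2 higher when adjusted over the list alone (median log2 change -0.47, camera adjusted p = 0.000345, and adjusted p = 0.289 with an estimated correlation). Besides Pou5f1 these were Klf5 (-1.57, SE 0.191, adjusted p = 0.00282), Dppa5a (-2.08, SE 0.344, adjusted p = 0.0136) and the glucose transporter gene Slc2a3 (-1.05, SE 0.167, adjusted p = 0.0115). Like Pou5f1, Dppa5a differed between hCD4 replicates 1 and 2 (1397 and 745), while Klf5 (637 and 599) and Slc2a3 (1937 and 2082) lay closer. Over the list the median log2 difference of these 2 arrays was 0.09 (replicate 1 minus replicate 2). Nanog, a core pluripotency factor, was at 165 ± 32.0 against 167 ± 9.04 (log2 change -0.02, SE 0.264, adjusted p = 0.986). A second probe set of Nanog had a log2 change of -1.49 (adjusted p = 0.137). In the primed epiblast list, 2 of 11 measured genes fell and 0 rose, by either adjustment, including adjusted over the list alone (median log2 change -0.29, camera adjusted p = 0.00508, and adjusted p = 0.289 with an estimated correlation). These were the transcription factor gene Sox4 (-0.92, SE 0.158, adjusted p = 0.0152) and the carbonic anhydrase gene Car4 (-0.77, SE 0.172, adjusted p = 0.0463). The primed epiblast call was also lost without Hemangioblast replicate 1 (adjusted p = 0.0761) and with dim probe sets left out (0.0545). Among the genes, Dppa5a lost its call without hCD4 replicate 1 (adjusted p = 0.0921), Slc2a3 and Sox4 without either hCD4 array (up to 0.118 and 0.13), and Car4 without any 1 array (up to 0.266). Car4 has another probe set with a log2 change of 0.19 (adjusted p = 0.784).

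In the primitive streak and nascent mesoderm list, 1 of 23 measured genes, Eomes, fell and 0 rose, with 2 lower and 1 higher when adjusted over the list alone. The list's shift missed the threshold (median log2 change -0.23, camera adjusted p = 0.054, and adjusted p = 0.309 with an estimated correlation). It passed with quantile normalization (0.0285), without scaling (0.0372) and without Hemangioblast replicate 2 (0.0326). Fgf8 was at 45.1 ± 10.5 against 177 ± 100 (adjusted p = 0.0846), Evx1 at 251 ± 50.8 against 424 ± 14.9 (adjusted p = 0.114), and Hand1, a gene of extraembryonic and lateral mesoderm, at 1372 ± 733 against 511 ± 95.8 (adjusted p = 0.0721). Another probe set of Hand1 was higher at an adjusted p of 0.0224. The brachyury gene T, which was to be reported whatever its value, was not analysed here. In the Hox and Cdx list, 0 of 24 measured genes passed in limma, over all probe sets or adjusted over the list alone, and 1 had an unadjusted p under 0.05 (median log2 change 0.12, camera adjusted p = 0.186, and adjusted p = 0.510 with an estimated correlation). Hoxa3, Hoxc8, Hoxc4 and Cdx2 had its smallest adjusted p-values, from 0.285 to 0.433.

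Endothelial genes moved both ways. Of 22 measured members, 3 rose and 2 fell, with 4 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.358, and adjusted p = 0.634 with an estimated correlation). The median log2 change was -0.19 and the test's direction was down, while the mean was 0.07. Vwf, which encodes von Willebrand factor of endothelium and megakaryocytes, rose from 44.8 ± 3.30 to 459 ± 9.08 (log2 change 2.97, SE 0.255, adjusted p = 0.000571), and the endothelial receptor gene Tie1 from 478 ± 110 to 1111 ± 96.7 (1.21, SE 0.196, adjusted p = 0.0128). Cd34 was the other member that rose. Kdr fell, and so did Flt4, another VEGF receptor gene, named after its values were seen (-0.94, SE 0.195, adjusted p = 0.0343). Another probe set of Vwf had a log2 change of 0.20 (adjusted p = 0.870), and Tie1 lost its call without hCD4 replicate 1 (adjusted p = 0.091).

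Genes of other lineages were tested as well. In the endoderm list, 4 of 26 measured genes fell and 0 rose, with 4 lower and 1 higher when adjusted over the list alone (median log2 change -0.24, camera adjusted p = 0.00795, and adjusted p = 0.289 with an estimated correlation). These were the basement membrane genes Col4a1 (-1.80, SE 0.211, adjusted p = 0.00238) and Lamb1 (-1.38, SE 0.224, adjusted p = 0.0130), the apolipoprotein gene Apoe (-0.92, SE 0.144, adjusted p = 0.0108) and the endodermal factor gene Gata6 (-0.89, SE 0.191, adjusted p = 0.0398). In the cardiac and smooth muscle list, 2 of 26 rose and 0 fell, with 3 higher and 2 lower when adjusted over the list alone, and the list had no settled direction. Its median log2 change was 0.00 (camera adjusted p = 0.863, and adjusted p = 0.897 with an estimated correlation), and its direction turned with quantile normalization, without the intensity trend and without hCD4 replicate 1. The members that rose were the troponin gene Tnni1 (1.52, SE 0.201, adjusted p = 0.00436) and the smooth muscle actin gene Acta2 (2.19, SE 0.353, adjusted p = 0.0124). In the neuroectoderm list, 0 of 26 genes passed in limma, over all probe sets or adjusted over the list alone, and 2 had an unadjusted p under 0.05 (median log2 change -0.05, camera adjusted p = 0.163, and adjusted p = 0.309 with an estimated correlation), and Cdh2 came nearest at an adjusted p of 0.0685. Without either hCD4 array, Apoe and Lamb1 lost their calls (up to 0.156 and 0.106), Gata6 lost its call without any 1 array (0.0731 to 0.213), and Acta2 without Hemangioblast replicate 1 or hCD4 replicate 2 (up to 0.0712).

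In the epithelial list, 1 of 21 measured genes rose and 2 fell, with 1 and 3 when adjusted over the list alone (median log2 change -0.21, camera adjusted p = 0.0501, and adjusted p = 0.355 with an estimated correlation). The p53 target gene Perp rose by 2.55 (SE 0.246, adjusted p = 0.000865), while the tight junction gene Tjp1 (-1.45, SE 0.184, adjusted p = 0.00348) and the protease inhibitor gene Spint1 (-1.79, SE 0.303, adjusted p = 0.0149) fell. The list passed with an added constant of 64 (0.0475), without the intensity trend (0.0433), with quantile normalization (0.0342), without scaling (0.0355), without Hemangioblast replicate 1 (0.0105) and without hCD4 replicate 2 (0.00428). The fibroblast feeder list covers the cells on which the ES cells were kept before differentiation. In it 3 of 27 measured genes rose and 1 fell, with 4 and 1 when adjusted over the list alone (median log2 change 0.17, camera adjusted p = 0.131, and adjusted p = 0.309 with an estimated correlation). Col3a1 (1.37, SE 0.256), the matrix protein gene Tgfbi (1.34, SE 0.260) and the chemokine gene Ccl2 (1.55, SE 0.327) rose at adjusted p-values of 0.0226, 0.0263 and 0.0372, and Fbln2 (-0.99, SE 0.204) fell at 0.0337. With 1 array left out, the adjusted p reached 0.113 for Spint1, 0.156 for Col3a1 and 0.128 for Tgfbi. Spint1 and Col3a1 lost their calls in every case but without Hemangioblast replicate 1, Tgfbi in every case but without hCD4 replicate 2, and Ccl2 and Fbln2 in all 4 (up to 0.172 and 0.263).

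Among signalling lists, BMP and TGF-beta responses had 2 of 22 measured genes higher and 4 lower, with 3 and 6 when adjusted over the list alone (median log2 change -0.31, camera adjusted p = 0.0406, and adjusted p = 0.297 with an estimated correlation). The BMP targets Id1 (-0.99, SE 0.171, adjusted p = 0.0164) and Id3 (-1.01, SE 0.163, adjusted p = 0.0124) and the activin receptor gene Acvr2b (-1.57, SE 0.169, adjusted p = 0.00154) fell, while Id2 rose by 1.45 (SE 0.248, adjusted p = 0.0156). The remaining called members, named after their values were seen, were Smad7, an inhibitor of the pathway, at 440 ± 64.3 against 892 ± 19.1 (adjusted p = 0.0168), and the ligand gene Tgfb1 at 1239 ± 298 against 560 ± 9.40 (adjusted p = 0.0169). The list's call was also lost with median scaling (adjusted p = 0.0784), without the intensity trend (0.0526) and without hCD4 replicate 1 (0.0608) or hCD4 replicate 2 (0.0732). In the Notch and Wnt list, 2 of 18 measured genes fell and 0 rose, with 3 and 0 when adjusted over the list alone (median log2 change -0.39, camera adjusted p = 0.00508, and adjusted p = 0.309 with an estimated correlation). These were the cyclin gene Ccnd1 (-1.31, SE 0.190, adjusted p = 0.00704) and Hes1, a target of Notch (-0.91, SE 0.206, adjusted p = 0.0477). Without either hCD4 array Id1, Id3 and Ccnd1 lost their calls (up to 0.131, 0.122 and 0.0717), Id2 did so without hCD4 replicate 2 (0.0909), and Hes1 without any 1 array (0.0983 to 0.245).

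Lists of growth, metabolism and stress were tested too. In the DNA replication and mitosis list, 0 of 27 measured genes passed in limma over all probe sets, 9 had an unadjusted p under 0.05, and 3 fell and 0 rose when adjusted over the list alone (median log2 change -0.26, camera adjusted p = 0.0013, and adjusted p = 0.289 with an estimated correlation). Mcm2, a subunit of the replicative helicase, came nearest at 774 ± 53.4 against 1226 ± 0.899 (-0.65, SE 0.150, adjusted p = 0.0502). In the glycolysis and hypoxia list, 2 of 23 measured genes fell and 0 rose, with 4 and 0 when adjusted over the list alone (median log2 change -0.17, camera adjusted p = 0.00867, and adjusted p = 0.289 with an estimated correlation). They were the hexokinase gene Hk2 (-1.10, SE 0.165, adjusted p = 0.00841) and Slc2a3. In the dissociation and stress list, 1 of 25 rose and 3 fell, with 2 and 3 when adjusted over the list alone (camera adjusted p = 0.619, and adjusted p = 0.639 with an estimated correlation). Its median log2 change was 0.02, while its mean was -0.01 and the test's direction was down, a direction that turned with quantile normalization. Fos (-1.26, SE 0.149, adjusted p = 0.00244), Myc (-1.18, SE 0.223, adjusted p = 0.0236) and the heat shock gene Hspa1b (-1.06, SE 0.230, adjusted p = 0.0410) fell, and Atf3 rose by 0.74 (SE 0.154, adjusted p = 0.0352). With 1 array left out the adjusted p reached 0.0798 for Hk2 and 0.118 for Slc2a3 (without either hCD4 array), 0.146 for Myc and 0.289 for Hspa1b (in every case but without Hemangioblast replicate 1), and 0.227 for Atf3 (in all 4).

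**Figure D3:**
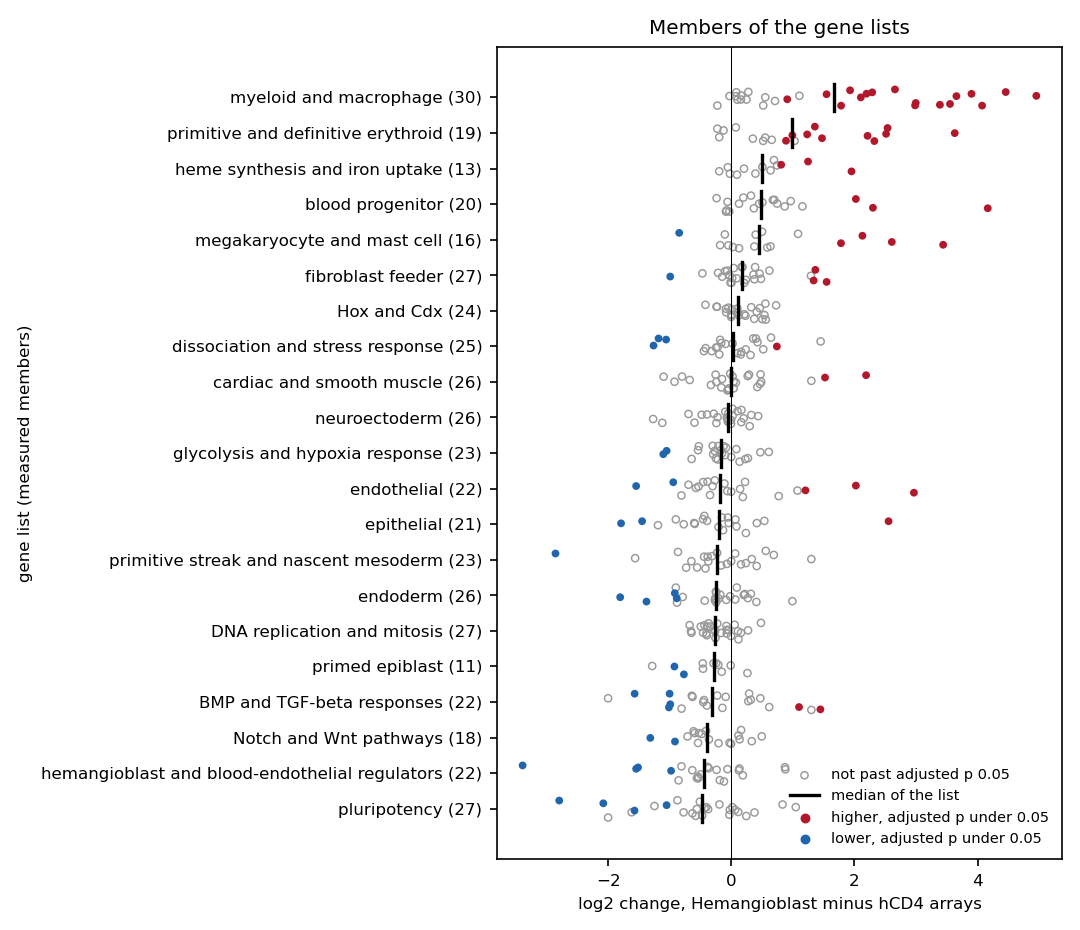
Log2 change (Hemangioblast minus hCD4) of the measured members of 21 gene lists, 1 point per gene, with red and blue for members higher and lower at an adjusted p under 0.05 and black bars at each list's median. The medians run from 1.67 for the myeloid and macrophage list to -0.47 for the pluripotency list.

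Of the 21 lists, 13 passed in camera with a preset correlation of 0.01 (5 up and 8 down), and 0 passed with a correlation estimated from the 4 arrays, where 2 had an unadjusted p under 0.05. The test with an estimated correlation has only 2 degrees of freedom, so few lists could pass it and the 0 does not show that the shifts are absent. Of 28 named genes past the threshold that have more than 1 probe set, 22 have another probe set that did not pass, and for 0 of them did another probe set pass in the opposite direction.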

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

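All alternatives were fixed before the data were examined, except that no scaling, and leaving out each array for the count of 2-fold pairs, were chosen after the results were seen. The count of 556 probe sets was 630 and 523 with an added constant of 1 or 64, 449 with median scaling, 490 with quantile normalization and 646 with dim probe sets left out. Without scaling between arrays it was 272, all among the 556 (222 higher, 50 lower), with 204 genes. It was 220 without the intensity trend, 178 with a minimum fold of 1.5, 359 by the 2-fold rule alone, and 219 to 517 with 1 array left out, where a lone array is assumed to vary like the other group. Those higher (362) came to 188, 148 and 170 to 283 without the trend, with the minimum fold and with 1 array left out. Those lower (194) came to 32, 30 and 42 to 234, and to 305 with dim probe sets left out, where fewer tests are corrected for. The count of 442 genes was 159 without the trend, 131 with the minimum fold, 260 by the 2-fold rule and 160 to 400 with 1 array left out. The 359 probe sets of the 2-fold rule became 884 at 1.5-fold, 99 at 4-fold and 538 to 727 with 1 array left out, where fewer pairs must pass. Fewer samples account for part of the falls with an array left out, and for the losses without the trend or without scaling the cause was not tested.

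The replicate number as a block gave 710 probe sets (432 higher, 278 lower), of which 551 were among the 556. Deviations from the group mean did not run together by replicate number across the groups over all probe sets (r = -0.0078), and the labels give the number no meaning, so the unblocked fit is the one reported. Some measures did differ alike by number in both groups: the trimmed mean intensity before scaling was 388 and 389 on the replicate 1 arrays and 345 and 334 on the others, the actin 3' to 5' ratio was 1.63 and 1.36 against 1.16 and 1.12, and the heme synthesis and epithelial lists differed in the same direction. A shared source of same-numbered arrays is therefore not excluded. With this block Tal1 (adjusted p = 0.0416), the epithelial list (0.0349) and the primitive streak list (0.0469) passed.

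In the test with an estimated correlation all 13 list calls were lost. The adjusted p was then 0.289 for pluripotency, primed epiblast, erythroid, myeloid, megakaryocyte, blood progenitor, endoderm, DNA replication and glycolysis. It was 0.297 for BMP and TGF-beta, and 0.309 for blood-endothelial regulators, heme synthesis and Notch and Wnt. The estimated correlations of the pluripotency (-0.00455) and endoderm (-0.0373) lists lay below the preset 0.01. Their unadjusted camera p still rose, from 6.58e-05 to 0.0464 and from 0.00417 to 0.0852. A larger correlation thus does not account for these losses. With an estimated correlation the test rests on the 2 residual degrees of freedom of the fit, which by itself raises the p of a list. For the other lists the effects of the correlation and of the degrees of freedom were not separated. The loss of the 13 calls therefore does not show that correlation between members explains the shifts. The BMP and TGF-beta call was also lost with median scaling (0.0784) and without the trend (0.0526), and ran from 0.0041 to 0.0732 with 1 array left out. The primed epiblast call was lost with dim probe sets left out (0.0545) and ran from 0.00247 to 0.0761. The epithelial list passed at an added constant of 64 (0.0475), without the trend (0.0433), with quantile normalization (0.0342) and without scaling (0.0355), and ran from 0.00428 to 0.395. The primitive streak list passed with quantile normalization (0.0285) and without scaling (0.0372) and ran from 0.0326 to 0.199. The cardiac and smooth muscle list turned down without the trend (0.967) and with quantile normalization (0.964) and ran from 0.318 to 0.818, turning down without hCD4 replicate 1 (0.543). The stress list turned up with quantile normalization (0.894). For these changes the cause was not tested.

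Of the 98 named genes, Nanog (log2 change -0.21 to 0.16) and Runx1 (-0.58 to 0.10) changed direction with an array left out, to 0.03 and 0.01 without hCD4 replicate 2, and 0 of the 69 past the threshold did so under any setting. Of these 69, 36 kept their calls under every setting that uses all 4 arrays and 41 without each array in turn. Without Hemangioblast replicate 1 or 2, 9 and 13 lost their calls, and without hCD4 replicate 1 or 2, 24 in each case. Signal near the floor limits dim genes, whose change depends on the added constant. Named genes on dim probe sets were not tested where dim probe sets were left out, so that setting does not count for them.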

Other observations

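Except for the myeloid and macrophage list, written before the data were examined, all tests of this part were chosen after the results were seen. So were the 4 gene lists described next. Lysosomal genes were higher on the Hemangioblast arrays, with 16 of 41 measured genes past the threshold and 0 lower, and 25 higher and 0 lower when adjusted over the list alone (median log2 change 0.67, camera adjusted p = 2.02e-15 over 4 lists, and adjusted p = 0.119 with an estimated correlation). The cathepsin gene Ctsb was at 5358 ± 81.0 against 1205 ± 19.4 (log2 change 2.14, SE 0.134, adjusted p = 0.000153), and Ctsd at 4836 ± 232 against 1173 ± 130 (2.03, SE 0.147, adjusted p = 0.000301). Interferon response genes were also higher, 12 of 35 with 0 lower, and 19 higher and 1 lower when adjusted over the list alone (median 0.82, camera adjusted p = 9.94e-12, and adjusted p = 0.119 with an estimated correlation). Usp18, which restrains interferon signalling, was at 377 ± 5.53 against 32.4 ± 10.7 (3.04, SE 0.296, adjusted p = 0.000895), and B2m, the light chain of class I major histocompatibility complexes, at 2793 ± 3.53 against 719 ± 62.8 (1.94, SE 0.145, adjusted p = 0.000333). Some macrophage markers moved the same way on these arrays: 17 of 30 genes of the myeloid and macrophage list were higher and 0 lower, Csf1r, Adgre1 and Tyrobp among them (median log2 change 1.67, and adjusted p = 0.289 with an estimated correlation). The 13 members that did not pass in limma include the macrophage genes Itgam (adjusted p = 0.360), Mrc1 (0.639) and C1qa (0.818), named after their values were seen.

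Ribosome biogenesis genes were lower, 13 of 46 measured with 0 higher, and 30 lower and 0 higher when adjusted over the list alone (median log2 change -0.61, camera adjusted p = 2.48e-20, and adjusted p = 0.119 with an estimated correlation). Tsr1 was at 705 ± 71.6 against 1450 ± 75.9 (log2 change -1.03, SE 0.156, adjusted p = 0.00915) and the nucleolar methyltransferase gene Nop2 at 682 ± 88.0 against 1380 ± 233 (adjusted p = 0.0198). Cholesterol synthesis genes were lower as well, 5 of 18 with 0 higher, and 11 lower and 0 higher when adjusted over the list alone (median -0.64, camera adjusted p = 4.54e-08, and adjusted p = 0.156 with an estimated correlation). These were Cyp51, Idi1, Hmgcs1, Tmem97 and Fdps, with log2 changes from -0.99 for Cyp51 (SE 0.181, adjusted p = 0.0204) to -0.69 for Fdps (SE 0.152, adjusted p = 0.0426). The 4 lists were picked because their members were seen among the calls, so their tests do not stand as independent evidence of a shift.

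Arrays of one group also differed by list. Of 42 medians of log2 differences (replicate 1 minus replicate 2, 21 lists in each group), 9 lay outside the central 95% of 2000 random lists matched in size and intensity. Between the 2 Hemangioblast arrays these were -0.31 for the myeloid, -0.20 for the erythroid, -0.23 for the heme synthesis, 0.28 for the epithelial and 0.16 for the BMP and TGF-beta list. Between the 2 hCD4 arrays they were -0.27 for the blood-endothelial regulators, -0.23 for the cardiac and smooth muscle, -0.21 for the heme synthesis and 0.22 for the epithelial list. The heme synthesis and epithelial lists thus differed in the same direction by replicate number in both groups. The random lists were drawn gene by gene, while estimated correlations within the real lists reached 0.399, which can widen their medians. How far the 9 exceed what correlated lists would give was not measured.

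On the arrays titled Hemangioblast, blood lineage genes were higher and 4 of 22 regulators of the hemangioblast stage, Kdr among them, were lower, and the labels leave open which population these arrays hold. Sorted Flk-1 and Scl positive cells on these arrays with undifferentiated ES cells on the others would put Kdr higher there. Its log2 change was -1.54 (SE 0.168), so that reading leaves this part of the pattern unexplained. Macrophages alone added to a population would lower erythroid genes with the share of the other cells. Of the erythroid genes past the threshold, 10 were higher and 0 lower, so the macrophage reading leaves the erythroid rise unexplained. Both values belong to the pattern and were seen before these tests were chosen, so neither is an independent test. Matching hCD4 in the titles and the study text leaves Blast for these arrays, so they may hold blast colonies and the others sorted cells. Under this reading a change would run from sorted cell to colony. No value outside the pattern that raised this reading tests it here, so it stays open. The titles were kept as the groups in every comparison.

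The 4 arrays can be split 2 against 2 in 3 ways, too few for a share under 0.05. The real split gave 556 probe sets and the highest of the others 0 in limma, so 1 of the 3 splits, the real one, gave as many. Each other split puts arrays of both titles in each group, so differences between the populations add to the spread within groups. The 0 therefore does not measure what chance would give.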
